A study of Mus musculus with 2 samples.

How the data were processed

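Small RNA of fewer than 30 nt from the midbrain of mouse embryos at embryonic day 10.5 was sequenced in 2 libraries, which the labels give as biological replicates 1 and 2 of 1 group, from pools of 69 and 51 embryos. The deposited files hold raw read counts per microRNA gene, 1 file per library, from reads that the authors aligned to mm10 and counted on the GENCODE M4 annotation, per the description deposited with each file. The aligner, its settings and the adapter trimming are not given in the sources used here. Each file has 1973 gene rows and 4 further rows that name no gene and hold the unmapped, multiply mapped, unassigned and ambiguous reads. Multiply mapped reads stand in a row of their own and are not in the gene counts, so a gene whose mature sequence occurs at another locus can lose reads.

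The files have 3 count columns without names, and the first equals the sum of the other 2 in every gene row, so that the latter were read as the strands. The second column holds 97.4% and 97.3% of the gene-assigned reads and was taken as the gene's strand, and the third as the opposite strand, which the deposited description does not state. By a rule fixed before the data were examined, the first count column was used because no column is named as the sense strand, and the strand columns were used as alternatives. Gene identifiers were matched without their version to GENCODE M21 on GRCm38, the same build as mm10, for symbols, coordinates, host genes and precursor sequences. Of the 1973 identifiers 1894 matched, and the 79 others held 4 reads in replicate 1 and 7 in replicate 2. Coordinates are 1-based. A gene was taken to share sequence when its precursor held a stretch of 20 bases found at another M21 microRNA locus, which was the case for 929 genes. M21 has 2202 microRNA genes, of which 308 are not in the counts.

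CPM values (reads per 1000000 gene-assigned reads) were computed, and means and SDs over the 2 replicates. The log2 ratio of replicate 2 over replicate 1 used 0.5 added reads and library sizes scaled by TMM (edgeR 4.0.16). Counting intervals of ratios are at 95%, as are Wilson intervals of shares. A gene counted as detected with at least 10 reads in both libraries. The comparison of replicates used genes of mean CPM 10 or more. The spread between replicates was given as the SD of log2 ratios, with a bootstrap over genes, and as the square root of edgeR's common dispersion in a model with an intercept only. The exact binomial test per gene (two-sided, genes with at least 10 reads in sum) was conditional on TMM-scaled library sizes and adjusted by Benjamini-Hochberg at 0.05. It compares 2 libraries and not conditions. The test and the counting intervals take each read as independent, which reads without molecular identifiers are not. On simulated counts with 200 changed genes this test called 70.0% of them at 1.5-fold (487 genes tested), 85.5% at 2-fold (490 tested) and 96.0% at 4-fold (487 tested). It called 1, 4 and 4 unchanged genes. The simulated counts had Poisson error only, and were scaled by the genes known to be unchanged and not by TMM. These rates hence do not apply to libraries that vary beyond counting error.

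The 18 gene lists were written before the data were examined, by symbol, and hold 236 genes, none in more than 1 list. They are let-7, mir-125/99/100, neural progenitor, neuronal, mir-17-92 and paralogs, pluripotency, Hox-embedded, erythroid, leukocyte, endothelial, heart and skeletal muscle, mesenchyme, epithelium, liver, sensory and endocrine, eye and choroid plexus, Dlk1-Dio3 imprinted and Sfmbt2 intron repeats. A list's median log2 ratio was set against 10000 random lists of the same size matched on 10 bins of expression. Adjacent genes on 1 strand within 10 kb were compared with 10000 permutations within such bins. Named genes followed a rule fixed in advance: the 10 highest by mean CPM, the 3 highest members of each list with a mean of at least 10 reads, and the 5 highest and 5 lowest log2 ratios among genes of mean CPM 10 or more. In the results, Mir137, Mir200c, Mir302c, Mir367, Mir299b, Mir496b, Mirlet7a-2, Mirlet7c-1, Gm24321, Gm25252, Gm25750 and Gm25927 were chosen after their values were seen. So were the other genes named only in the closing section.

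Alternatives were DESeq2 size factors (DESeq2 1.42.0) and total counts for scaling, other expression filters, thinning of the deeper library, the strand columns, leaving out the most abundant gene or the genes that share sequence, leaving out each replicate, neighbour distances of 1 and 50 kb, and, for list medians, the mean ratio of each group of neighbours as 1 value. DESeq2 size factors shifted every log2 ratio by 0.03 relative to TMM. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3. Reads were not realigned, mature arms and isomiRs were not separated because the counts are per gene, and no test between conditions was made because there is 1 group. For 1 pattern weighed in the closing section, few reads at multi-copy microRNAs, low abundance at this stage was not tested, because no value in these counts could have spoken against it.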

Results

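MicroRNA abundance was profiled in the midbrain of mouse embryos (strain B6NCrl) at embryonic day 10.5, a stage at which the neural tube is built mostly of dividing neuroepithelial cells. The series holds 1 group of 2 biological replicates, each a library of RNA shorter than 30 nt from the pooled midbrains of 69 embryos (replicate 1) and 51 embryos (replicate 2) of both sexes. There is no second tissue, stage or treatment, so the design gives an abundance profile and the agreement of the replicates, and no contrast between conditions. The replicate 1 library held 7810040 reads, of which 3297835 (42.2%, 95% Wilson interval 42.2 to 42.3%) were assigned to 1 of the 1973 counted microRNA genes. The replicate 2 library held 9423767 reads, of which 3682410 (39.1%, 39.0 to 39.1%) were assigned. Reads that mapped to several places made up 30.9% and 29.5% of the libraries. Unmapped reads numbered 1639109 and 2287117, and uniquely mapped reads outside the counted genes made up 5.89% and 7.20%. The intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

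The profile was led by Mir335, Mir99a and Mir17, which together held 28.8% ± 0.203 (SD, n = 2) of the gene-assigned reads. Mir335 (ENSMUSG00000065501.1, chr6:30741299-30741396, mm10, in an intron of the imprinted gene Mest) was the most abundant gene at 127345 ± 22571 CPM (reads per 1000000 gene-assigned reads; SD, n = 2). Mir99a (ENSMUSG00000065530.1, chr16:77598936-77599000, an intron of Mir99ahg) followed at 81041 ± 25592 CPM. Mir17 (ENSMUSG00000065508.1, chr14:115043671-115043754, in an exon of Mir17hg, the host transcript of the mir-17-92 polycistron) had 80045 ± 994 CPM. The difference between Mir99a and Mir17 was smaller than the spread of Mir99a between the replicates, and their order was the opposite in replicate 2. The next genes were Mir130a (ENSMUSG00000065484.1, chr2:84741115-84741178, intergenic) at 35213 ± 1167 CPM, Mir20a (ENSMUSG00000065442.1, chr14:115044157-115044263, Mir17hg exon) at 31949 ± 799 CPM and Mir100 (ENSMUSG00000093011.1, chr9:41531425-41531504, an intron of 3110039I08Rik) at 29749 ± 6919 CPM. Mir126a (ENSMUSG00000065540.1, chr2:26591357-26591429), which lies in Egfl7 and is known from endothelium, had 28615 ± 3062 CPM. Mir26b (ENSMUSG00000065468.1, chr1:74394310-74394394, an intron of Ctdsp1) had 27055 ± 1917 CPM. The last of the 10 were Mir92b (ENSMUSG00000076255.2, chr3:89227116-89227198, intergenic), known from neural progenitors, at 23299 ± 2904 CPM and Mir99b (ENSMUSG00000065396.1, chr17:17830188-17830257, an intron of Spaca6) at 23296 ± 2997 CPM.

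These 10 genes held 48.8% ± 0.443 (SD, n = 2) of the gene-assigned reads and the 50 most abundant genes 83.3% ± 0.628. At least 10 reads in both libraries were counted for 399 genes, at least 1 read in both for 621, and no read in either for 1204. In both libraries, 104 genes reached 1000 CPM and 19 reached 10000 CPM. The values apply to genes as counted, which differ from mature microRNAs in that a gene's reads come from both arms of its precursor. Reads mapped to several places, 30.9% and 29.5% of the libraries, are also not in them. The order and the shares given here hence hold for gene-assigned reads only, and microRNAs with copies at other loci can rank too low.

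Of 18 lists of microRNA genes fixed before the data were examined, which together held 55.8% ± 1.75 of the gene-assigned reads (SD, n = 2), the mir-17-92 cluster and its paralogs held the largest share. The 15 members of this list, made from 3 related polycistrons known from dividing embryonic cells, held 19.8% ± 0.863, led by Mir17, Mir20a and Mir93 (20207 ± 294 CPM). The 6 members of the mir-125/99/100 family list held 13.9% ± 3.67, nearly all of it from Mir99a, Mir100 and Mir99b. The list of the imprinted Dlk1-Dio3 cluster of chromosome 12 held 6.87% ± 0.0451 over 45 members matched by symbol, 42 of them at a mean of 10 CPM or more. Mir496b, a member without reads, lies on chromosome 19. The most abundant members of the list were Mir487b at 9933 ± 156 CPM, Mir369 at 6858 ± 119 CPM and Mir411 at 6668 ± 564 CPM. Mir409, Mir376a and Mir380 of the same region are not among the counted genes. Gm24321, Gm25252 and Gm25750 overlap them in turn on the other strand and are in no list. They had 11105 ± 1461, 2093 ± 363 and 1466 ± 86.2 CPM, all on what was taken as the strand opposite to them. If these reads come from the cluster, its share is understated and Mir487b is not its most abundant gene. The reads of 1 further member, Mir299b, lay almost wholly on what was taken as the strand opposite to the gene.

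Lists of neural microRNAs held less. The neural progenitor list held 4.70% ± 0.385 of the gene-assigned reads (SD, n = 2), with Mir92b, Mir181c (6925 ± 1843 CPM) and Mir181d (5550 ± 1763 CPM) at its head. The neuronal list, which takes in microRNAs of neurons and mature brain, held 1.13% ± 0.0477, led by Mir219a-2 (5151 ± 606 CPM), Mir219a-1 (2063 ± 353 CPM) and Mir153 (1905 ± 704 CPM). The let-7 list has 9 members, matched by symbol, of a family whose mature forms accumulate as tissues differentiate. It held 0.669% ± 0.306, with 4382 ± 2026 CPM for Mirlet7g, 1759 ± 873 CPM for Mirlet7i and 353 ± 98.8 CPM for Mirlet7d. Mirlet7e is not among the counted genes, and Gm25927, which overlaps it on the other strand and is in no list, had 6732 and 5064 reads, all on what was taken as the strand opposite to Gm25927. The pluripotency list, made from the mir-302 and mir-290 clusters of embryonic stem cells, held 2.43% ± 1.36, with Mir302a at 9468 ± 5372 CPM, Mir302d at 7339 ± 3907 CPM and Mir302b at 6109 ± 3606 CPM. Reads mapped to several places are not in these values, and 28 of the 43 members of the let-7, neural progenitor and neuronal lists share a stretch of 20 bases with another microRNA locus. Without the genes that share sequence, the neuronal list held 0.361% and the pluripotency list 0.962%, because Mir219a-1 and Mir219a-2 share sequence with each other or other loci, as do Mir302a and Mir302b.

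Markers of other cell types were present at various levels. Mir126a alone, the endothelial list, made up 2.86% ± 0.306 of the gene-assigned reads (SD, n = 2). The mesenchyme list held 1.51% ± 0.217, led by Mir143 (7426 ± 1296 CPM), Mir214 (3871 ± 375 CPM) and Mir140 (3279 ± 401 CPM). The sensory and endocrine list held 0.680% ± 0.116, with Mir182 at 2657 ± 89.7 CPM, Mir183 at 2357 ± 748 CPM and Mir375 at 944 ± 267 CPM. The epithelium list held 0.374% ± 0.0492, with Mir205 at 1342 ± 183 CPM, Mir429 at 829 ± 232 CPM and Mir203 at 769 ± 145 CPM. The rodent repeat microRNAs of the Sfmbt2 list held 0.722% ± 0.0909, led by Mir467c (2680 ± 510 CPM), Mir467d (1799 ± 258 CPM) and Mir467e (1357 ± 85.9 CPM), and 67 of its 69 members share sequence with other loci, so that their values are uncertain, and without the genes that share sequence the list held 6.34e-05%. Blood cell lists were small. The erythroid list held 0.0389% ± 0.00212, with Mir451a at 325 ± 41.5 CPM, Mir144 at 37.9 ± 8.19 CPM and Mir486 at 26.2 ± 12.1 CPM. The leukocyte list held 0.137% ± 0.0124, with Mir142b at 773 ± 129 CPM, Mir223 at 312 ± 2.05 CPM and Mir155 at 272 ± 2.58 CPM. All reads of Mir142b lay on what was taken as the opposite strand, and the leukocyte list held 0.0607% when only same-strand reads were counted. The eye and choroid plexus list held 0.0326% ± 0.0111 and the list of microRNAs embedded in the Hox clusters 0.0278% ± 0.0165. Heart and skeletal muscle microRNAs held 0.00672% ± 0.000672, with Mir208b at 33.9 ± 4.24 CPM, Mir206 at 10.3 ± 0.413 CPM and Mir208a at 8.47 ± 0.457 CPM. Mir122, the hepatocyte microRNA, made up 0.00105% ± 0.000668, with 19 reads (0.000576%) in replicate 1 and 56 reads (0.00152%) in replicate 2.

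**Figure D1:**
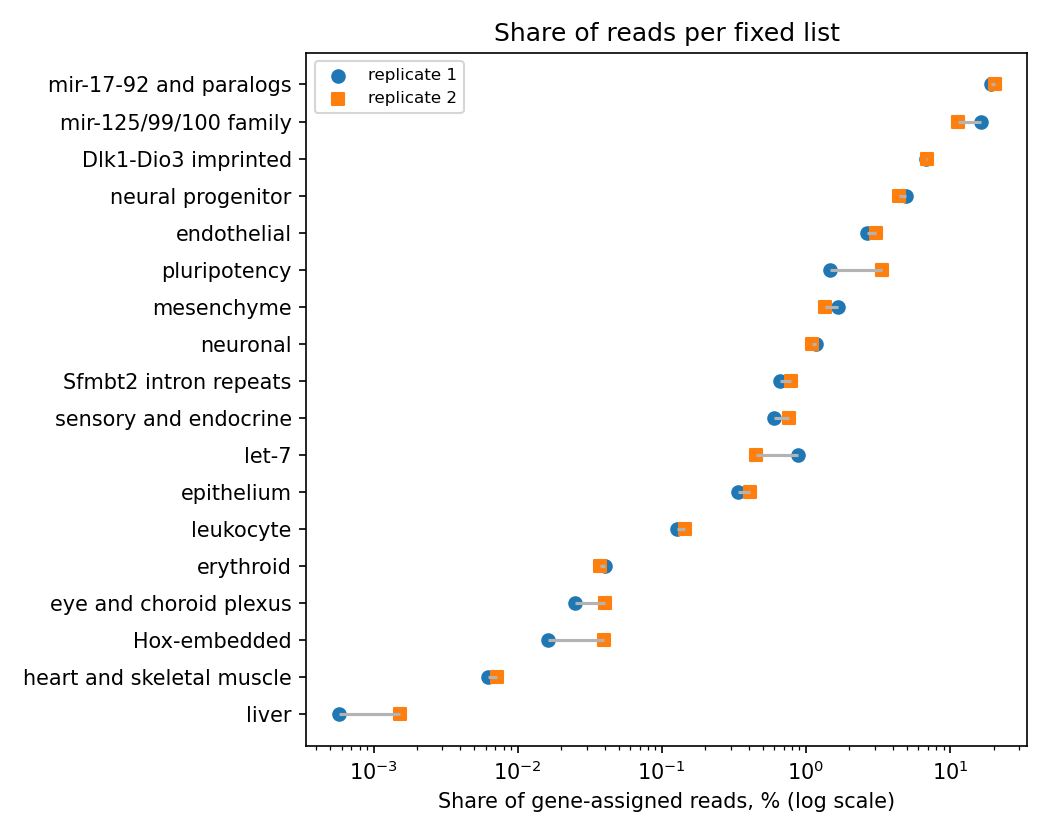
Share of gene-assigned reads held by each of the 18 fixed lists (x axis, percent, log scale), with a circle for replicate 1, a square for replicate 2 and a line joining them. The mir-17-92 list is highest at 19.2% and 20.4%, and the pluripotency list is at 1.47% in replicate 1 and 3.39% in replicate 2.

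Most genes had similar values in the replicates, but not to within counting error. Among the 338 genes of mean CPM 10 or more, Pearson's r of log2 CPM was 0.984 and Spearman's rho 0.986 across genes, which are not independent replicates. The ratio of replicate 2 to replicate 1 lay within 1.5-fold for 280 of them (82.8%), exceeded 2-fold in 18 and was lower by more than 2-fold in 7. The SD of the log2 ratio was 0.57 (95% bootstrap interval 0.45 to 0.69), against 0.15 expected from counting alone. The biological coefficient of variation from edgeR's common dispersion was 0.240 (95% bootstrap interval 0.207 to 0.269, 485 genes), with 1 residual degree of freedom per gene, and the median of gene-wise DESeq2 dispersions gave 0.0875. Both bootstrap intervals resample genes of the same 2 libraries as if independent, so they do not cover the spread among further pools. With 1 library per pool, the coefficient cannot tell differences in library preparation from those between pools. An exact binomial test on the reads of the 2 libraries, which compares those libraries and not conditions, found 241 of 485 genes beyond counting noise at a Benjamini-Hochberg adjusted level of 0.05, 112 higher and 129 lower in replicate 2. With DESeq2 size factors the numbers were 120 higher and 115 lower. The test takes reads as independent, which those without molecular identifiers are not. The numbers called, here and in the lists below, can therefore be too high. For the same reason the SD expected from counting can be too low and the counting intervals below too narrow. Of the 170 list members tested, 124 passed when adjusted over all genes and 123 when adjusted over the list alone.

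**Figure D2:**
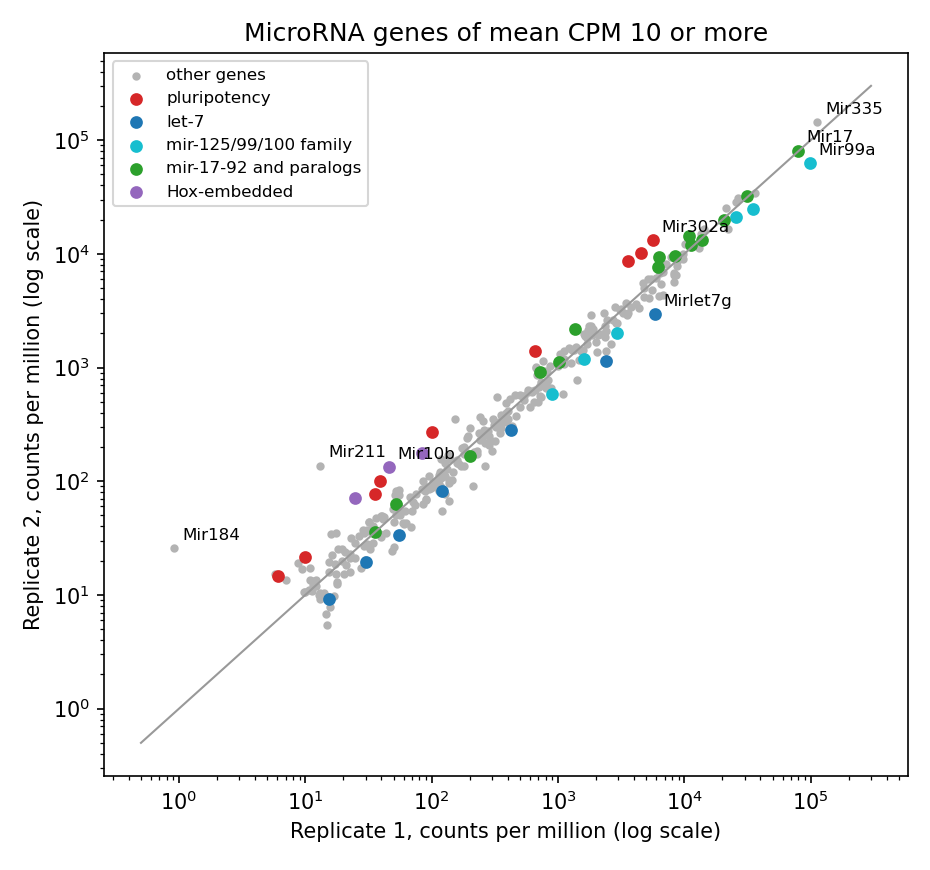
CPM of each microRNA gene of mean CPM 10 or more in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), coloured for 5 of the fixed lists and the diagonal marking equal values. The pluripotency and Hox-embedded genes lie above the diagonal, and the let-7 and mir-125/99/100 genes below it.

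Among genes of mean CPM 10 or more, Mir184 had the highest ratio, with 3 reads in replicate 1 and 95 in replicate 2, a ratio of 24.5 with a 95% counting interval of 8.44 to 71.2. Mir211, which lies in an intron of Trpm1 (chr7:64205806-64205911) and is known from pigment cells, had 43 and 504 reads, 10.4-fold higher in replicate 2 (counting interval 7.65 to 14.2). Mir10b, Mir196b and Mir293 followed and were 2.90-, 2.84- and 2.68-fold higher in replicate 2. The lowest ratios belonged to Mir448 (49 and 20 reads, log2 ratio −1.43), Mir7b (−1.22), Mir138-1 (−1.15), Mir181b-2 (−1.09) and Mir383 (48 and 25 reads, −1.08), and Mir448 lies in an intron of Htr2c.

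Differences between the pools were shared by most members of several lists. In replicate 2 the pluripotency list was higher in all 9 members of mean CPM 10 or more, with a median log2 ratio of 1.23 and a range of 1.09 to 1.42, and its share was 2.31 times that of replicate 1. All 10000 random lists matched on expression had a lower median. Its genes lie in 2 groups of neighbours, and with 1 value per group the median of 1.22 was within the central 95% of random lists (percentile 95.6). The binomial test called 10 of its 11 tested members, all 10 higher, and the same number when adjusted over the list alone. The Hox-embedded list was higher in all 3 of its 6 members that reached a mean CPM of 10, Mir10b, Mir196b and Mir10a (log2 ratios 1.08 to 1.54, percentile 99.8 of random lists). Its median was that of Mir196b, and the binomial test called 4 of 5 tested members, all higher. The sensory and endocrine list had a median of 0.59 (percentile 99.8, 3 of 4 members higher, with Mir182 at −0.06). The epithelium list had 0.54 (percentile 99.7, 5 of 7 higher), with Mir200c highest at 0.73 and Mir203 at −0.38. With 1 value per group of neighbours it had 0.25 (percentile 93.7), within the central 95%. The eye and choroid plexus list had 1.79 (percentile 99.4), but rests on 2 genes that differ, Mir211 at 3.38 and Mir204 at 0.19. The test called 4 of 4 sensory and endocrine members (3 higher, 1 lower), 7 of 7 epithelium members (5 higher, 2 lower) and both genes of the eye and choroid plexus list, higher.

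Lists of neural and differentiation-related microRNAs were lower in replicate 2. All 7 let-7 members of mean CPM 10 or more were lower, with a median log2 ratio of −0.71 (percentile 0.02 of random lists), and the 9 tested members were called lower by the binomial test, adjusted over all genes or over the list alone. The mir-125/99/100 list was lower in 6 of 6 members with a median of −0.50 (percentile 0.135). In the neural progenitor list, 10 of 11 members had a log2 ratio below 0 (median −0.55, percentile 0.01), and the exception was its most abundant member, Mir92b, at 0.26. In the neuronal list, 13 of 17 had a log2 ratio below 0 (median −0.44, percentile 0.135), with Mir153 at −0.77 and Mir137 at −0.86, while Mir219a-1 and Mir219a-2 were at 0.36 and 0.25. The binomial test called 6 of 6 members of the mir-125/99/100 list, all lower, 10 of 11 neural progenitor members (9 lower, 1 higher) and 11 of 20 neuronal members (9 lower, 2 higher). These counts, and those of the lists higher in replicate 2, were equal when adjusted over the list alone. The shares of the latter 2 lists hence differed less than the medians of their genes, by ratios of 0.890 and 0.942.

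In 9 of the 16 lists with 2 or more members of mean CPM 10 or more, the median lay outside the central 95% of random lists, where 0.8 are expected for genes that vary independently. The other 7 lay within it. These were the mesenchyme list at −0.30 (percentile 6.75, all 6 members lower), mir-17-92 and paralogs at 0.12 (percentile 70.5), Dlk1-Dio3 at 0.02 (percentile 82.5), heart and skeletal muscle at 0.17 (percentile 63.7), the Sfmbt2 repeats at 0.21 (percentile 95.6), erythroid at 0.45 (percentile 97.4) and leukocyte at −0.01 (percentile 52.9). The erythroid median was equal to the upper limit of its range, also without genes that share sequence (percentile 97.55). The test called 7 of 7 mesenchyme members, all lower, 13 of 15 of mir-17-92 and paralogs (10 higher, 3 lower) and 28 of 43 of Dlk1-Dio3 (16 higher, 12 lower). It called 3 of 3 erythroid members (2 higher, 1 lower), 1 of 4 leukocyte, 6 of 16 Sfmbt2 and 1 of 5 muscle members, the latter 8 all higher. Adjusted over the list alone, no muscle member passed and the counts of the others were equal. The leukocyte median was positive, 0.03, with DESeq2 size factors. With 1 library per pool and no further replicate, the percentiles describe these libraries only and carry no p-value. Some list members are neighbours, a link that the random lists do not keep. With 1 value per group of neighbours, an alternative chosen after the data were seen, 7 lists lay outside. Of these, the let-7 and mir-125/99/100 lists are not independent. Mir99a is grouped with Mirlet7c-1 and Mir100 with Mirlet7a-2, and these groups enter both lists.

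**Figure D3:**
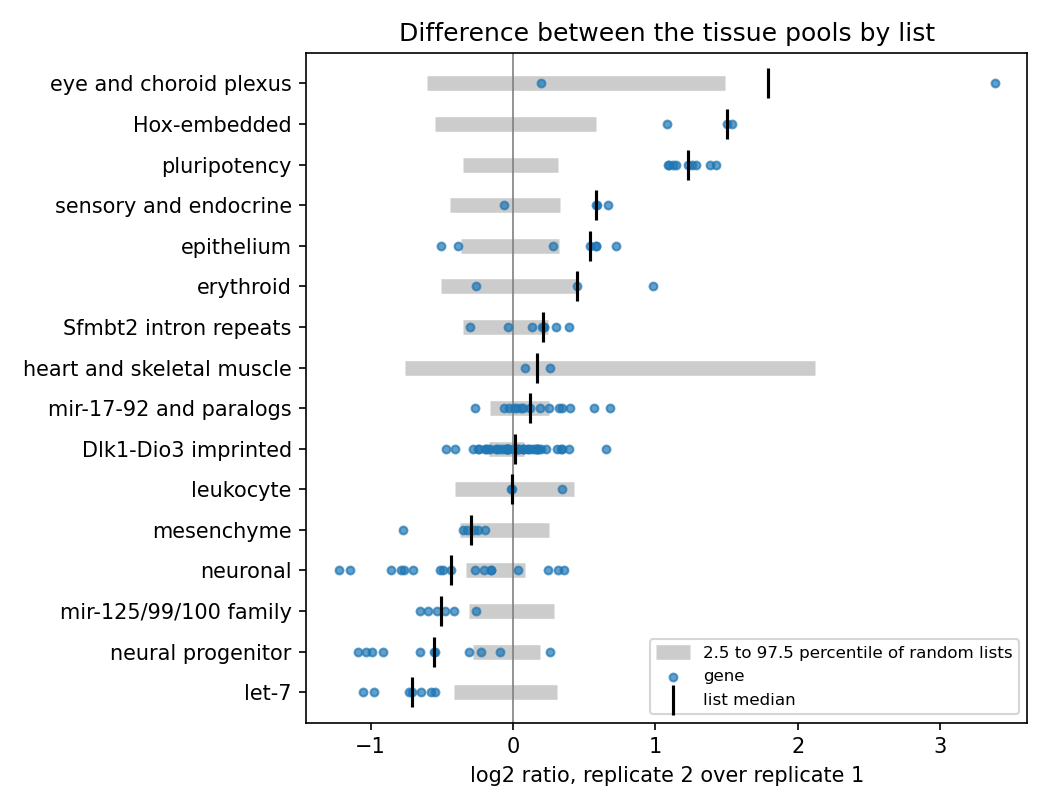
Log2 ratio of replicate 2 over replicate 1 (x axis) for the genes of 16 fixed lists, with a point per gene of mean CPM 10 or more, a black bar at the list median and a grey band over the central 95% of the medians of 10000 random lists matched on expression. The medians of 5 lists lie above the band, up to 1.79, and those of 4 lists below it, down to −0.71.

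Neighbouring microRNA genes differed between the pools in the same way. For 107 pairs of adjacent genes on 1 strand less than 10 kb apart, the log2 ratios of the members of a pair differed by 0.25 on average. After permuting the ratios among genes of like expression the mean was 0.52 (95% of permutations between 0.42 and 0.62), and none of the 10000 permutations was as small as the observed value. Without the Dlk1-Dio3 list, an alternative chosen after the data were seen, 66 pairs differed by 0.28 on average, against 0.57 after permutation. In the mir-302 cluster of chr3:127545228-127545807, the genes had log2 ratios of 1.23 (Mir302a), 1.29 (Mir302b), 1.09 (Mir302c) and 1.15 (Mir302d), and Mir367, with 13 and 25 reads and below the CPM limit of the pairs, had 0.76.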

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

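All tests in this part were chosen after the result was seen.

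Reads on the strand opposite to the counted gene were flagged because the main values rest on the sum of both strands, with the strand columns used only as alternatives. Which column is the opposite strand was inferred from the share of reads. They made up 2.613% of gene-assigned reads in replicate 1 and 2.723% in replicate 2. They were concentrated at 9 genes with at least 100 such reads in replicate 1, which held 99.6% of them. The first is Gm24321 (chr12:109743158-109743237), with 33216 and 44699 opposite-strand reads and 0 same-strand reads in both libraries, at the position of Mir409 on the other strand. Gm25301 lies likewise opposite Mir378a (15781 and 18431 reads), Gm24083 opposite Mir191 (8110 and 9683), Gm25252 opposite Mir376a (7749 and 6764), Gm25927 opposite Mirlet7e (6732 and 5064), Mir299b opposite Mir299a (5241 and 5223), Gm25750 opposite Mir380 (5035 and 5173), Mir142b opposite Mir142 (2250 and 3184) and Mir497b opposite Mir497 (1659 and 1637).

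Loss of strand information in the libraries is argued against, because the median share of opposite-strand reads was 0% in the 262 other genes with a mean of at least 100 reads. A candidate explanation is that these reads come from microRNA genes on the other strand that the counted gene set lacks. The test was the share of opposite-strand reads at genes overlapping an M21 microRNA on the other strand, and it was 99.83%, at 32 genes whose partners are all missing from the counts. On this hypothesis the reads listed for Gm24321, for instance, may be those of Mir409. No biological explanation was tested, because the design has 1 group.

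Reads mapped to several places were flagged because the comparisons leave them out. They made up 30.89% of all reads in replicate 1 and 29.45% in replicate 2, and 39.0% ± 0.147 of mapped reads (SD, n = 2).

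Some multi-copy microRNAs had few reads. Mir124a-1, Mir124a-2 and Mir124a-3, known from neurons, had 7, 56 and 16 reads in replicate 1 and 2, 36 and 34 in replicate 2, and Mir9-2 had 3 and 4 and Mir9-3 452 and 246, while Mir92-1 (27563 and 35013) and Mir219a-2 (15572 and 20546), which also share sequence, had many. A candidate explanation is that reads shared between copies were left out of the gene counts. It was tested within 23 groups of neighbouring genes that hold both kinds, where members sharing 20 bases with another locus had a median log2 CPM difference of −3.581 from the others (0.1 CPM added; lower in 19 groups; two-sided sign-flip permutation p = 0.0351). Without the 5 groups that hold let-7, neural progenitor or neuronal genes, the difference was −2.62 with a permutation p of 0.124, so the result rests in part on the lists that prompted it, and low abundance of these genes at this stage remains open.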

How the results depend on the processing

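Among the alternatives, the same-strand column outside the shares of lists and of the 10 most abundant genes, the leaving out of a replicate for the genes detected, for the latter share and for single genes, the 4 further settings for list medians, and the leaving out of the imprinted list were chosen after the data were seen. No list median outside the range of random lists changed its direction, and directions of single genes were not compared. Scaling shifts a list and its random lists alike, so it could not alter the percentiles of list medians. Without genes that share sequence and in the same-strand column, the 9 lists outside the range of random lists stayed outside it, as did at CPM 100 or more the 7 of them with 2 or more genes left. Without genes that share sequence, the erythroid median (0.45, percentile 97.55) was equal to the upper limit of the range and not above it. With 1 value per group of neighbours, the pluripotency list (1.22, from 2 values) and the epithelium list (0.25) fell within the range of random lists. The sensory and endocrine list (percentile 99.9) and the eye and choroid plexus list (percentile 98.7), also with 2 values, stayed outside it. Genes beyond counting noise numbered 224 to 240 under 6 alternatives, against 241, with more of them lower than higher in replicate 2 (129 and 112) except with DESeq2 size factors (115 and 120), and neighbouring genes stayed below the permuted range under all 4. Without the most abundant gene, the share of the 10 most abundant was 43.6%, and list shares were 5.38% (neural progenitor), 1.30% (neuronal), 22.7% (mir-17-92), 3.28% (endothelial), 1.73% (mesenchyme) and 7.88% (Dlk1-Dio3), because the total is smaller by construction. Without genes that share sequence, shares were 0.361% (neuronal), 20.6% (mir-17-92), 0.962% (pluripotency), 5.69% (Dlk1-Dio3) and 6.34e-05% (Sfmbt2 repeats), because members or part of the total are left out. The share of the 10 most abundant genes was 50.1% in the same-strand and 99.7% in the opposite-strand column. With at least 1 read, 621 genes were detected. The SD of log2 ratios was 0.75 at CPM 1 or more, 0.41 at CPM 100 or more and 1.15 without a filter, where counting alone gives 1.19, and scaling cannot alter it. The DESeq2 median dispersion gave a coefficient of variation of 0.0875 against 0.240, and the cause was not tested. Depth limits the ratios of rare genes most, as for Mir184, where 3 reads in replicate 1 leave a counting interval of 8.44 to 71.2.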

Other observations

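The tests of the let-7 and mesenchyme lists as explanations in this part were chosen after the result was seen, and the GC test was set before.

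Several abundant microRNAs belong to none of the fixed lists, and those named here were chosen after their values were seen. Mir30e (chr4:120772606-120772697, an intron of Nfyc) had 19272 ± 4106 CPM (SD, n = 2) and Mir30a 12156 ± 1272 CPM. Mir322 on chromosome X had 15400 ± 1480 CPM and Mir130b 14235 ± 1093 CPM. Others lie in introns of protein-coding genes, which are Nsrp1 for Mir423 (9382 ± 634 CPM), Map2k4 for Mir744 (8918 ± 67.6 CPM), Ptk2 for Mir151 (8598 ± 1116 CPM), Gpc1 for Mir149 (8259 ± 607 CPM) and Evl for Mir342 (7547 ± 989 CPM).

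Genes made from 1 polycistron differed widely in counted reads, and whether their levels in the tissue differ as much was not tested. In the mir-17-92 cluster (chr14:115043671-115044506), Mir17 had 1512 times the CPM of Mir19b-1 in replicate 1 and 1293 times in replicate 2, and the log2 ratios of its 6 members between pools ran from −0.27 to 0.26. In the mir-302 cluster, Mir302a had 1438 and 1954 times the CPM of Mir367, a gene with few reads, and the log2 ratios ran from 0.76 to 1.29. In the cluster of Mir106a and Mir363 on chromosome X they ran from 0.01 to 0.68. Mir19b-1 shares sequence with another locus, whereas no shared stretch of 20 bases was found for Mir367 or for Mir19a, which had 182 ± 24.1 CPM in the mir-17-92 cluster.

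The median of the pluripotency list was higher and those of the neural lists were lower in replicate 2. With 1 value per group of neighbours, however, the pluripotency median of 1.22 was within the central 95% of random lists (percentile 95.6). The shares of the neural progenitor and neuronal lists differed less than their medians, by ratios of 0.890 and 0.942. GC content of the precursor is argued against, since after a lowess fit on GC the pluripotency median was still 1.289, above the range of random lists of single genes, and r between GC and the log2 ratio was 0.029 across 338 genes. A smaller neural share with every other cell type raised alike would raise the mesenchyme list too. Its median was −0.2977 with all 6 members lower, at −0.77 to −0.19, and the pluripotency members were at 1.09 to 1.42. These values argue against an equal rise only. The mesenchyme median was within the range of random lists (percentile 6.75), so a fall of that list is not shown. A smaller neural share with other cell types raised unequally was not tested. An earlier average stage of the tissue in replicate 2 is a candidate explanation, since the let-7 median was −0.7061, below the range of random lists, but this was found and tested on the same data. No let-7 value was predicted for the explanations left untested here, so this median cannot tell an earlier stage from them. Differences in dissection, which might add the surface, eye or hindbrain tissue known for Mir211, Mir184, Mir205 and the Hox-embedded genes, and in library preparation, for which the labels used here give no batch, stay open and untested.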
